A study of Mus musculus with 4 samples.

How the data were processed

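Ventricle nuclei of 4 mice were profiled by sci-RNA-seq, a combinatorial indexing method in which the barcode of a nucleus is put together from indices added in successive rounds. Per the labels, the hearts were frozen 14 days after myocardial infarction, and 2 came from control animals (Ctl) and 2 from animals with loss of function of MBNL1 (KO), an RNA-binding protein that regulates splicing. The deposited matrices hold the count of unique molecular identifiers (UMIs) per gene and barcode, as whole numbers with no normalization. STAR, Seurat, GRCm38 and mm10 are named per the submitters' processing notes, with versions not given in the sources used here. The gene table held 38014 entries, of which 37940 matched GENCODE vM21 on GRCm38 and 7 were constructs (Cre, eGFP, Mbnl1-tg, Mercremer, tdTomato, Tnnc1-i61q and Tta). Symbols that stood on more than 1 entry numbered 87.

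Barcodes with at least 300 UMIs, at most 10% mitochondrial UMIs and fewer than 10 times the library's median UMIs were kept as nuclei. Counts were scaled to 1000 UMIs per nucleus and log transformed, 1997 variable genes and 30 principal components were used, and a graph of 15 neighbours was clustered by Leiden at a resolution of 0.6, giving 23 clusters (scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3; plots with matplotlib 3.10.9). Clusters were named from marker lists. The limits of the naming rule were set after the data were seen. A name needed at least 3 markers over 1.5 times their level in barcodes under 50 UMIs, here called empty barcodes. The geometric mean ratio of the list to that level had to be at least 1.3. Clusters were called background-rich where the highest list stood under 5 times that level and markers of another major class stood over 0.6 times it. The major classes were cardiomyocytes, fibroblasts, endothelial cells and macrophages. Background-rich clusters, clusters with markers of 2 classes and a cluster led by cell cycle genes stayed unnamed and were kept out of the classes. Doublets were scored with Scrublet at an expected rate of 6% and 30 neighbours. It marked 1, 5, 3 and 6 nuclei in Ctl 1, Ctl 2, KO 1 and KO 2, too few for the method to have worked, and none were left out.

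UMIs were summed per animal over cardiomyocytes, fibroblasts, endothelial cells, macrophages and all nuclei, since the animal was the unit of replication. A class needed at least 50 nuclei in every animal. KO was compared with Ctl with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test, two-sided, adjusted by Benjamini-Hochberg over all genes tested) in R 4.3.3 with limma 3.58.1. A gene was called at an adjusted p under 0.05. The genotype effect in cardiomyocytes was set against that in all other nuclei, unnamed clusters included, as an interaction term. Levels are CPM, a gene's UMIs over all UMIs of the sum on the usual scale of edgeR without TMM factors, given as mean ± SD of 2 animals, and log2 folds are KO over Ctl ± SE. The SE was the size of the log2 fold over the square root of F and was left out where F was close to 0. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Members were also adjusted over the list alone. Shares of nuclei per class were fitted with edgeR on the counts of nuclei. Shares of nuclei with cell cycle transcripts were taken after thinning each nucleus to 300 UMIs, with Wilson 95% intervals and a two-sided exact permutation test, whose smallest p over 4 animals is 0.333. Intervals and limits cover counting error only. Where a group had a count of 0, its limit was taken from 3 counts.

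Comparisons, gene lists, tests, most alternatives and the rule for named genes were chosen before the data were examined. The rule took Mbnl1, Mbnl2 and Mbnl3 in every class and, where fewer than 5 genes passed the adjusted threshold, the 5 genes with the smallest p, leaving out sex linked genes and gene models without a name. From each list called by camera, it took up to 4 members that passed, over the list alone where none passed over all genes, and otherwise the 3 members with the highest mean level. In classes other than cardiomyocytes, members were named for the lists with the smallest p. Lists of genes and markers come from general knowledge, not from these samples. The same pipeline was tested on simulated sums, drawn from the means, depths and spread of the real ones with some genes changed. Each simulated gene took the spread between animals that the trend over level gave. Genes that vary more than this trend were not simulated. Of genes changed 4-fold, 84.8% were called in cardiomyocytes, 86.4% in fibroblasts, 92.4% in endothelial cells, 83.3% in macrophages and 86.4% in all nuclei. Of genes changed 2-fold, 28.4% were called in cardiomyocytes. For class shares, 1 simulation per fold changed 2 classes, and 2 were called at 4-fold and 0 at 2-fold.

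The barcodes showed that the replicate 1 libraries of both groups shared rows of reverse transcription wells, and that the replicate 2 libraries shared others. A fit with the replicate number as a block was therefore made for each comparison. Alternatives were the DESeq2 1.42.0 Wald test, its size factors in edgeR, library totals alone, no filterByExpr, minimums of 500 and 1000 UMIs, a limit of 5% mitochondrial UMIs, sums thinned to the smallest, the replicate block and leaving out each animal. After the data were seen, further alternatives were added. These were leaving out the nuclei with the highest 6% of doublet scores and taking wide classes. Genes above their level in empty barcodes and named classes alone as the other nuclei were the others. Wide classes took in the background-rich clusters. For cardiomyocytes they also took in a cluster with markers of 2 classes, whose highest marker list was that of atrial cardiomyocytes. Splicing was not analysed here, since the matrices count UMIs per gene. The 2 mice per group give no correlation across samples, and none was computed. Over genes at 20 CPM or more, the log2 difference of replicate 1 from replicate 2 was correlated between Ctl and KO. The correlation ran from 0.36 in cardiomyocytes to 0.77 in fibroblasts, so the replicates shared differences across the groups. The mix of clusters within the fibroblast class also went with the replicate number. In Ctl 1, Ctl 2, KO 1 and KO 2 the class joined 687, 1207, 4361 and 1689 nuclei with 1439, 6981, 7933 and 8008 of another cluster. The cause of the shared differences was not tested.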

Results

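RNA was measured in nuclei of the ventricles of 4 mice, 2 control (Ctl) and 2 MBNL1 loss-of-function (KO), 14 days after myocardial infarction. Ctl 1, Ctl 2, KO 1 and KO 2 gave 16772, 50976, 80269 and 65762 nuclei, 213779 in all. The median UMIs per nucleus were 1151, 1108, 1534 and 1008, and the median genes 700, 674, 892 and 619. Total UMIs per library were 38503582, 102167112, 277283809 and 131523322, of which 81.8%, 86.6%, 76.9% and 81.4% lay in nuclei. Cardiomyocyte sums held 6450843, 13253779, 20721057 and 10531414 UMIs from 2380, 5288, 4750 and 4349 nuclei. Fibroblast sums held 3245533, 12851556, 26522116 and 13031577 UMIs, endothelial sums 1706089, 2151909, 7690168 and 2549016, and macrophage sums 2250790, 5853085, 15129284 and 5802955.

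Mbnl1 (ENSMUSG00000027763, GRCm38 chromosome 3, 60472830 to 60629750, plus strand) was read in every library at similar levels in both groups. In the cardiomyocyte sums its level was 710, 622, 753 and 707 CPM in Ctl 1, Ctl 2, KO 1 and KO 2 (666 ± 62.5 in Ctl and 730 ± 32.0 in KO, SD), a log2 fold of 0.12 ± 0.15 (SE). In all nuclei it was 821, 600, 802 and 632 CPM, a log2 fold of 0.01 ± 0.22. The log2 fold of Mbnl1 was 0.07 ± 0.27 in fibroblasts, 0.04 ± 0.24 in endothelial cells and -0.34 ± 0.39 in macrophages, where Ctl 1 stood at 2065 CPM and the other libraries at 1073, 1390 and 1065. UMIs counted per gene need not see the deleted part of a gene, so these levels check nothing about the genotype. Mbnl2, the paralog expressed in the same cells, had log2 folds of -0.13 ± 0.18 in cardiomyocytes, -0.04 ± 0.20 in fibroblasts, -0.08 ± 0.22 in endothelial cells, -0.07 ± 0.27 in macrophages and -0.18 ± 0.18 in all nuclei. Mbnl3 stood at 1.49 ± 0.35 CPM in Ctl and 1.56 ± 0.86 in KO cardiomyocytes (0.08 ± 0.51), with log2 folds of 0.40 ± 0.26 in fibroblasts, -0.09 ± 0.54 in endothelial cells, 0.02 ± 0.39 in macrophages and 0.22 ± 0.23 in all nuclei. None of the 3 genes was called in any class by edgeR.

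**Figure D1:**
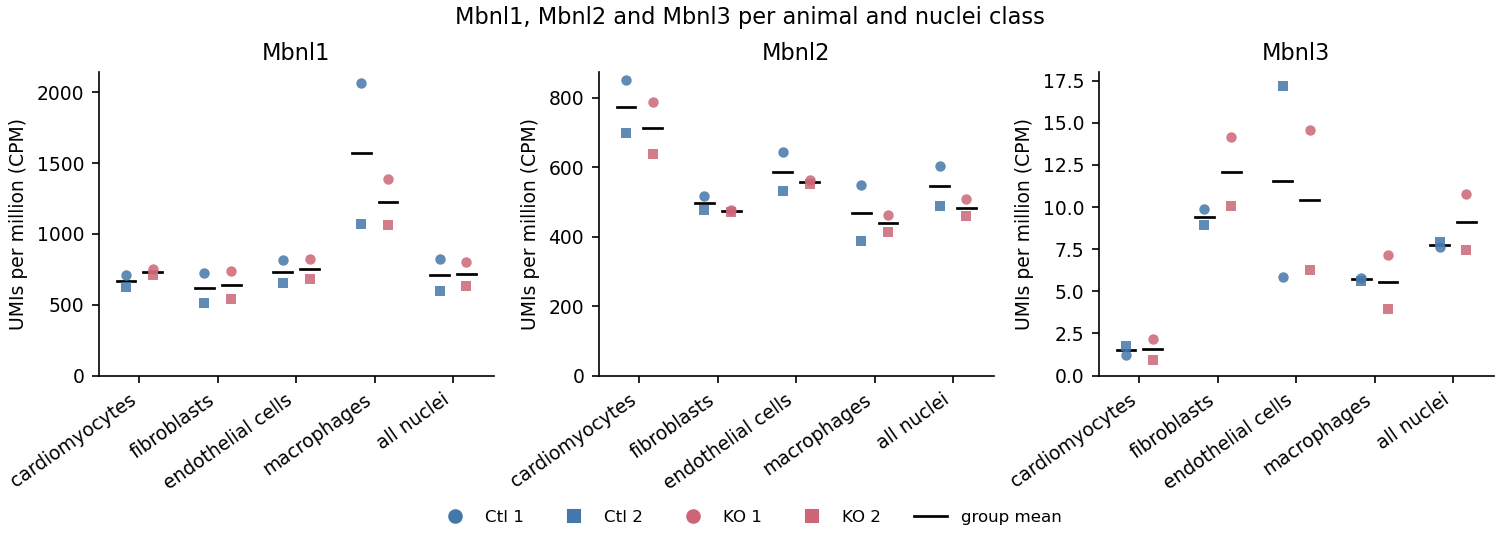
Levels of Mbnl1, Mbnl2 and Mbnl3 in CPM (vertical axis from 0) per nuclei class (horizontal axis), with a point per animal and a black line at the mean of the 2 animals of a group. Mbnl1 in cardiomyocytes ran from 622 to 753 CPM over the 4 animals.

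The animals of the control group differed in construct transcripts. Mercremer, a Cre recombinase whose activity depends on tamoxifen, stood at 0 CPM in Ctl 1 and at 54.7, 39.5 and 30.8 CPM in Ctl 2, KO 1 and KO 2. The count of 0 in Ctl 1 allows up to 0.0952 CPM. A Tnnc1 construct, Tnnc1-i61q, stood at 0.35 CPM in Ctl 1 and at 307, 174 and 168 CPM in the others. Reads of eGFP were at 0 in Ctl 1, 103 CPM in Ctl 2, 0.038 in KO 1 and 0.028 in KO 2. Mercremer UMIs were in 0, 23.3, 31.9 and 17.5% of cardiomyocyte nuclei and in 0, 1.53, 1.497 and 0.577% of fibroblast nuclei, at median UMIs of 2128.5, 1906, 3477 and 1797 in cardiomyocytes and 1117, 1095, 1506.5 and 905 in fibroblasts. KO against Ctl therefore set 2 animals with transcripts of both Mercremer and the Tnnc1 construct against 1 animal with them (Ctl 2) and 1 with none or nearly none (Ctl 1), so every KO over Ctl value here holds any effect of these constructs as well as that of MBNL1 loss. Values without Ctl 1 compare animals that all had both, with eGFP at over 100 CPM in Ctl 2.

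The genotype effect in cardiomyocytes addressed the role of MBNL1 in cardiomyocyte maturity and entry into the cell cycle after infarction. Genes of the fetal and stress program were higher in KO as a group, with 13 of 14 members positive and a median log2 fold of 0.70 (adjusted p = 1.8e-06; adjusted p = 0.745 with an estimated correlation). Ankrd1, a stretch-responsive protein of the sarcomere, was at 786 ± 416 CPM in Ctl and 1670 ± 64.5 in KO (log2 1.08 ± 0.36). Myh7, the slow myosin heavy chain of the fetal heart, was at 817 ± 337 and 1329 ± 327 CPM (0.69 ± 0.33). The sums left out an unnamed cluster of 18730 nuclei with markers of 2 classes. Xirp2, Nppa and Acta1, members of the fetal and stress list, were among its leading genes. The lists were not tested with that cluster counted in. The mature sarcomere and membrane list showed no shift, with 9 of 20 members positive (adjusted p = 0.975).

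Single genes in cardiomyocytes did not pass the threshold. The 5 with the smallest p had both KO values outside the range of Ctl. Malt1, a paracaspase of NF-kB signaling on chromosome 18 (65430938 to 65479067), was at 249 ± 35.3 CPM in Ctl and 712 ± 55.4 in KO (log2 1.51 ± 0.17, adjusted p = 0.945). Dapp1, an adaptor that binds phosphoinositides, was at 17.1 ± 2.5 and 47.8 ± 1.1 CPM (1.48 ± 0.18, adjusted p = 0.945). Dennd2c, a protein with a DENN domain, was at 2.88 ± 0.76 and 12.97 ± 0.87 CPM (2.21 ± 0.27, adjusted p = 0.945). Strit1, the small membrane peptide DWORF that promotes SERCA activity, was at 8.62 ± 2.11 and 1.87 ± 0.18 CPM (-2.25 ± 0.31, adjusted p = 0.958). Sfrp2, a secreted modulator of Wnt signaling, was at 22.1 ± 2.5 and 50.9 ± 1.2 CPM (1.19 ± 0.17, adjusted p = 0.958), which is 0.127 times its level in empty barcodes. Dapp1, Dennd2c, Strit1 and Sfrp2 lie on chromosome 3, as does Mbnl1, while that chromosome held 776 of the 14957 genes tested. Of these 776 genes, 7 had p under 0.01 against 5.66 expected, a count that cannot tell about a shorter stretch. Within 10 Mb of Mbnl1, 3 of 130 genes had p under 0.01 over all nuclei against 1.12 expected, Strit1 among them. Whether a stretch of chromosome 3 differs between the groups was not tested in cardiomyocytes. edgeR called 0 of 14957 genes, with 618 at an unadjusted p under 0.05, and DESeq2 called 16, 7 higher and 9 lower. The edgeR count was 9 without Ctl 1, 274 without Ctl 2, 2 without KO 1, 3 without KO 2 and 0 with the replicate number as a block. In simulated data 5.97% of genes changed 1.5-fold and 28.4% of genes changed 2-fold were called, against 84.8% of genes changed 4-fold. Changes of 1.5-fold and 2-fold were thus mostly not detectable at this depth and group size. Simulated genes had the spread of the trend, while Dennd2c and Strit1, at log2 folds of 2.21 and -2.25, were not called. The simulated share at 4-fold may thus be too high for the real genes.

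Fibrillar matrix and activated fibroblast genes were higher in KO in the cardiomyocyte sums, with 25 of 27 members positive and a median log2 fold of 0.73 (adjusted p = 6.7e-16; adjusted p = 0.745 with an estimated correlation). Col3a1, a fibrillar collagen, was at 328 ± 219 CPM in Ctl and 493 ± 14.1 in KO, Col1a2 at 250 ± 144 and 453 ± 34.6, and the matrix glycoprotein Sparc had a log2 fold of 0.53 ± 0.39. All 27 members lay below their level in empty barcodes, where the median of the list was 0.69, and fibroblast markers stood higher in the same sums (10 of 12 positive, median 0.36, adjusted p = 0.0089, and adjusted p = 0.757 with an estimated correlation). Both KO values lay above both Ctl values in 17 members, where chance gives 1 in 6 of genes.

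In the fetal and stress program Xirp2, an actin-binding protein of the intercalated disc, was at 1341 ± 646 CPM in Ctl and 2455 ± 1129 in KO. Of its 14 members, 8 lay below their level in empty barcodes, where the median of the list was 0.396, and 6 at or above it, all positive with a median of 0.78. Hypoxia genes had 13 of 14 members positive and a median of 0.38 (adjusted p = 0.00033; adjusted p = 0.745 with an estimated correlation). In this list Kdm3a, a histone demethylase induced by hypoxia, had a log2 fold of 0.40 ± 0.14 and Vegfa, the endothelial growth factor, 0.15 ± 0.35. Egln1, the oxygen sensor prolyl hydroxylase, was at 99.6 ± 8.9 CPM in Ctl and 100.1 ± 3.9 in KO, with a log2 fold of 0.0003 that was -0.0080 with DESeq2 size factors. The recruited and inflammatory myeloid list had 11 of 11 members positive and a median of 0.48 (adjusted p = 3.0e-05; adjusted p = 0.745 with an estimated correlation). Its most abundant members were Hif1a, the hypoxia-inducible transcription factor found in most cell types (386 ± 106 and 599 ± 71.5 CPM), Fn1, the matrix glycoprotein fibronectin (0.92 ± 0.36), and Apoe, a lipid carrier (0.51 ± 0.25). Of the 11 members of the myeloid list, 10 lay below their level in empty barcodes, where the median of the list was 0.27. Macrophage markers were higher in the same sums, with 10 of 12 positive and a median of 0.30 (adjusted p = 0.042, and adjusted p = 0.757 with an estimated correlation).

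Fatty acid oxidation genes were lower in KO cardiomyocytes, with 22 of 24 members negative and a median of -0.24 (adjusted p = 9.3e-06; adjusted p = 0.745 with an estimated correlation). Lpl, which frees fatty acids from lipoproteins, was at 2522 ± 96.4 CPM in Ctl and 1826 ± 90.0 in KO (-0.47 ± 0.16), the fatty acid transporter Cd36 had a log2 fold of -0.13 ± 0.19 and the coactivator Ppargc1a 0.15 ± 0.39. Of its members 13 lay below their level in empty barcodes, where the median of the list was -0.48, and the 11 at or above it had a median of -0.16. This call ended without KO 1 (adjusted p = 0.134). Oxidative phosphorylation genes had 28 of 31 negative and a median of -0.18 (adjusted p = 0.00098; adjusted p = 0.745 with an estimated correlation; adjusted p = 0.0586 without Ctl 2). Atp5a1 and Atp5b, subunits of the ATP synthase, had log2 folds of -0.23 ± 0.15 and -0.24 ± 0.16, and Sdha, of complex II, -0.05 ± 0.22. Of the 31 members 29 lay below their level in empty barcodes, where the median was -0.288. Calcium handling and conduction genes had 15 of 23 negative and a median of -0.17 (adjusted p = 0.0148; adjusted p = 0.745 with an estimated correlation). The most abundant of them did not follow the list, with log2 folds of 0.26 ± 0.27 for the sodium-calcium exchanger Slc8a1, 0.02 ± 0.21 for the calcium release channel Ryr2 and 0.28 ± 0.20 for the phosphodiesterase Pde4d. The calcium call ended without Ctl 1 (adjusted p = 0.323), KO 1 (0.144) and KO 2 (0.0534). Cardiomyocyte markers had 6 of 14 positive and a median of -0.05 (adjusted p = 0.586).

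Interferon response genes were lower in KO cardiomyocytes, with 10 of 15 negative and a median of -0.26 (adjusted p = 0.0231; adjusted p = 0.745 with an estimated correlation). Rsad2, an antiviral enzyme induced by interferon, was at 14.8 ± 0.80 CPM in Ctl and 7.30 ± 0.66 in KO (-1.03 ± 0.19), and all 15 members lay below their level in empty barcodes, where 13 were positive and the median was 0.123. This call ended with the replicate block (adjusted p = 0.106), in thinned sums (0.291), without Ctl 2 (0.546) and without KO 1 (0.436). Adjusted over the list alone, 1 interferon gene (Rsad2) and 1 gene of the hypertrophic signaling list (Adra1b) passed, both lower, against 0 over all genes, and 0 passed in the other lists. Adra1b, the alpha-1B adrenergic receptor, was at 92.0 ± 27.3 CPM in Ctl and 39.7 ± 4.2 in KO (-1.22 ± 0.24), while the hypertrophic signaling list had 10 of 21 positive (adjusted p = 0.676). With the replicate block, 8 matrix genes and 7 fetal and stress genes passed over the list alone.

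Of 27 lists in cardiomyocytes 8 were called, 14 without Ctl 2 and 5 without KO 1. In those not called, adjusted p was 0.0881 for G2 and M phase, 0.128 for resting fibroblast, 0.210 for S phase, 0.290 for angiogenic and tip endothelium, 0.351 for nuclear retained, 0.450 for TGF beta signaling and 0.477 for glycolysis. It was 0.496 for cardiac growth regulators, 0.597 for ribosomal proteins, 0.676 for cell cycle inhibitors, 0.791 for antigen presentation and 0.862 for resident macrophage, mitochondrially encoded and capillary and arterial endothelium genes. It was 0.870 for immediate early and heat shock, 0.975 for splicing regulators and 0.987 for the MBNL family. The median and the mean differed in sign for cardiac growth regulators (-0.03 and 0.07), antigen presentation (0.04 and -0.01), resident macrophage (0.10 and -0.02), capillary endothelium (-0.01 and 0.01), immediate early (0.09 and -0.02), splicing regulators (0.02 and -0.01) and mature sarcomere (-0.03 and 0.01). The camera direction was up for the first 5 of these, and down for splicing regulators, mature sarcomere and the MBNL family, whose median was 0.08 and mean 0.03. With the replicate block, resting fibroblast genes passed (adjusted p = 0.0433; adjusted p = 0.956 with an estimated correlation and no block).

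**Figure D2:**
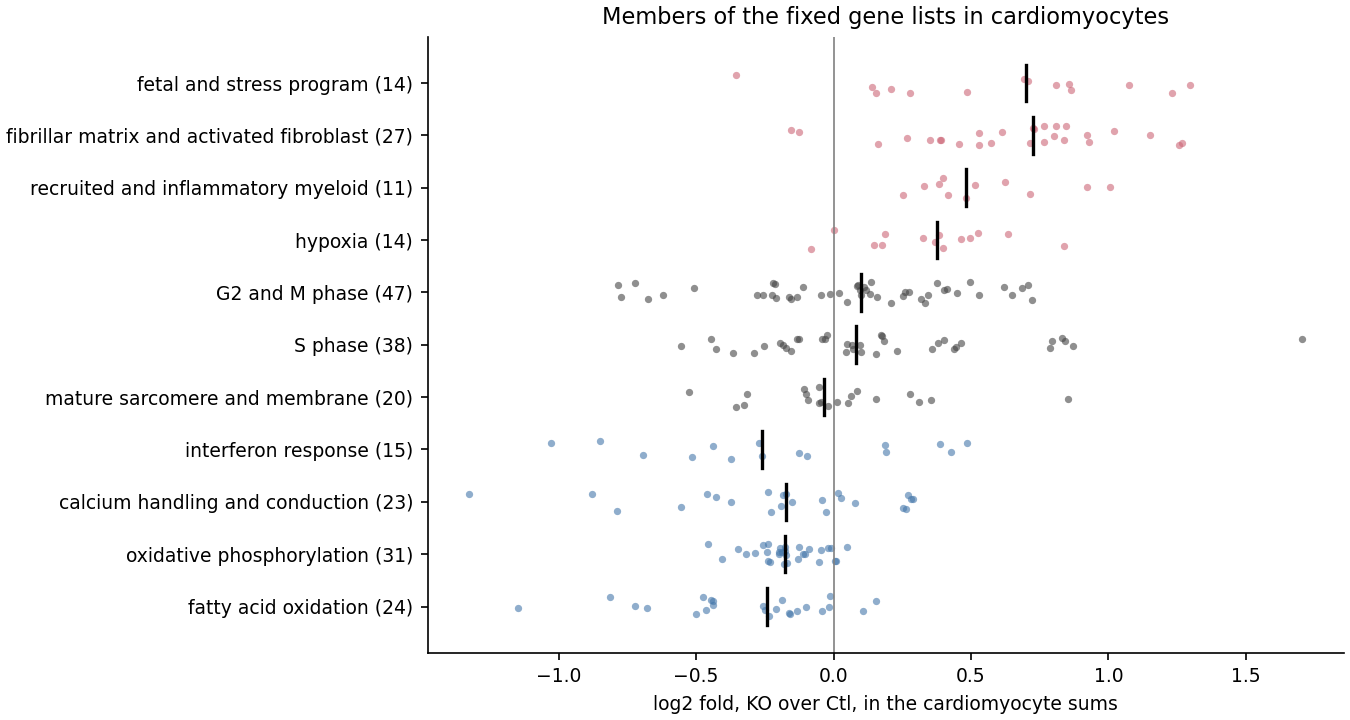
Log2 fold, KO over Ctl, in the cardiomyocyte sums (horizontal axis) of each tested member of 11 gene lists (vertical axis, number of members in brackets), with a black line at the list's median. Points are red or blue where camera called the list higher or lower and grey where it did not, and medians ran from -0.26 for interferon response to 0.73 for fibrillar matrix.

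Set against the effect in all other nuclei, the effect in cardiomyocytes differed for Dennd2c, which lies on chromosome 3 (103102604 to 103169769). The other nuclei were all those outside the cardiomyocyte class, so they were not free of cardiomyocytes. They held an unnamed cluster of 24684 nuclei with cardiomyocyte markers at 1.62 times their level in empty barcodes. Mercremer stood at 42.2, 30.9 and 23.9 CPM in the other nuclei of Ctl 2, KO 1 and KO 2. Dennd2c stood at 3.41, 2.34, 12.4 and 13.6 CPM in Ctl 1, Ctl 2, KO 1 and KO 2 cardiomyocytes and at 14.5, 8.33, 12.3 and 10.2 CPM in the other nuclei. The difference between the effects was 2.15 ± 0.28 on the log2 scale (adjusted p = 0.0269), the 1 gene called of 18662, with 614 at an unadjusted p under 0.05. Without Ctl 1, Ctl 2, KO 1 and KO 2 the counts were 28, 579, 2 and 3. With fibroblasts alone as the other nuclei, or named classes alone, 0 genes passed in edgeR, with 523 and 502 at an unadjusted p under 0.05. Mbnl1 had a difference of 0.14 ± 0.22. In simulated data, 41.8% of genes changed 2-fold in cardiomyocytes alone were called, with no change in the other nuclei.

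Cell cycle transcripts in cardiomyocytes addressed entry into the cell cycle. G2 and M phase genes had 29 of 47 members positive and S phase genes 23 of 38, with medians of 0.10 and 0.08, and neither list passed. The G2 and M phase list passed with the replicate block (adjusted p = 0.0240; adjusted p = 0.987 with an estimated correlation and no block) and turned with the animal left out, being lower without Ctl 1 (2.4e-06) and higher without Ctl 2 (5.2e-10) and without KO 2 (0.0368). The S phase list was higher without Ctl 2 (adjusted p = 0.0141) and without KO 2 (0.0018). After thinning to 300 UMIs, nuclei with at least 1 UMI of the G2 and M phase list made up 8.15% of cardiomyocytes in Ctl 1 (Wilson 95% interval 7.12 to 9.32), 10.9% in Ctl 2 (10.04 to 11.7), 10% in KO 1 (9.18 to 10.9) and 10.4% in KO 2 (9.52 to 11.3). The means were 9.503 ± 1.91% and 10.2 ± 0.28% (exact permutation p = 1.0). Shares in fibroblasts were higher, at 16.1 ± 2.8% and 16.8 ± 0.75%, and in adipocytes they were 9.52, 26.2, 23.8 and 24.5% at median UMIs of 845.5, 1019, 1202 and 780. The cardiomyocyte shares lay below those of adipocytes in each library. In Ctl 1 the adipocyte share rested on 42 nuclei, and its Wilson 95% interval of 3.77 to 22.1 covered the cardiomyocyte share. This cannot tell background from cycling cardiomyocytes, since cycling of adipocytes was not tested. Nuclei with at least 1 S phase UMI made up 7.95 ± 0.49% and 7.78 ± 0.63% (exact permutation p = 0.667). With at least 2 UMIs the shares were 1.00 ± 0.64% and 1.01 ± 0.09% for G2 and M phase (exact permutation p = 1.0). For S phase they were 0.418 ± 0.003% and 0.643 ± 0.162% (exact permutation p = 0.333, the smallest possible). Thinned to 500 UMIs, the S phase shares turned, at 1.38 ± 0.23% in Ctl and 1.19 ± 0.34% in KO. All these shares left out the cluster led by cell cycle genes, so they say nothing of its nuclei. Part of that cluster had cardiomyocyte markers as its highest list. With that part added, at 300 UMIs, shares with at least 2 G2 and M phase UMIs were 1.57 ± 1.39% and 2.69 ± 0.54% (exact permutation p = 0.667). Per animal they were 0.588, 2.56, 3.07 and 2.31% in Ctl 1, Ctl 2, KO 1 and KO 2.

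**Figure D3:**
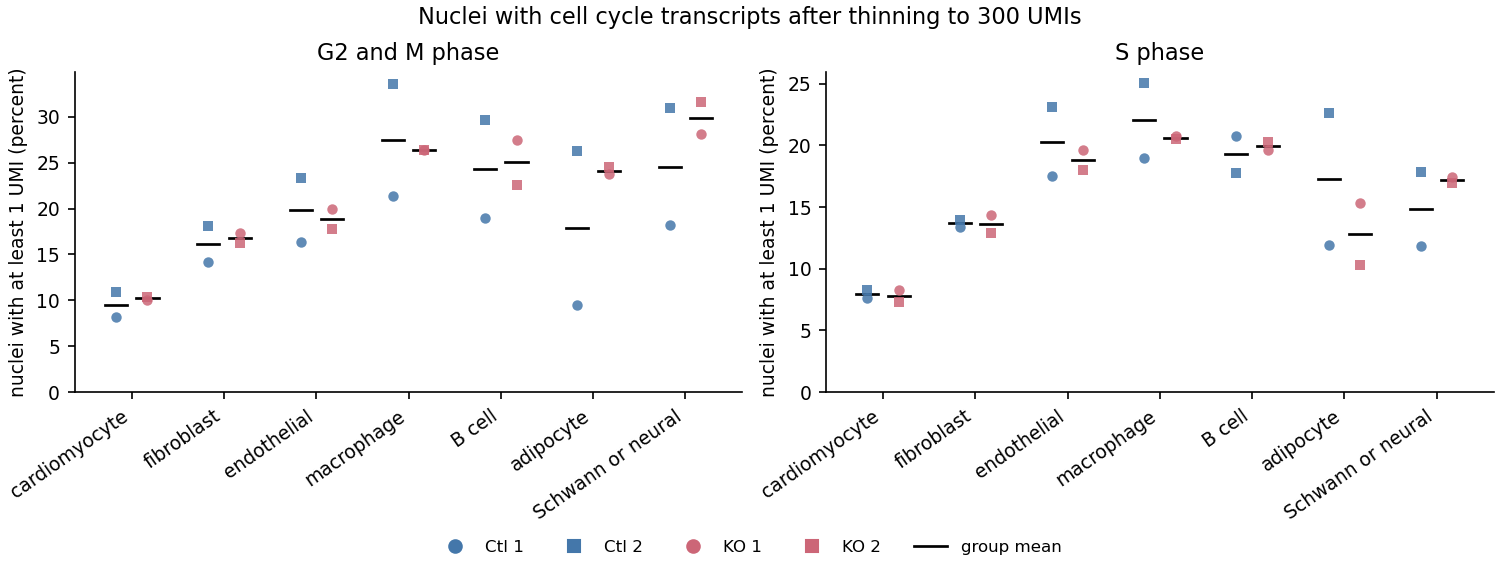
Share of nuclei with at least 1 UMI of the G2 and M phase list or of the S phase list after thinning to 300 UMIs (percent, vertical axis) per class (horizontal axis), with a point per animal and a black line at the group mean. In cardiomyocytes the G2 and M phase shares lay between 8.15 and 10.9% in the 4 animals.

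A cluster led by cell cycle genes held 242 nuclei whose highest marker list was that of cardiomyocytes. That list stood at 1.28 times its level in empty barcodes, against 2.48 times in the cardiomyocyte class. These nuclei lay under the minimum of 1.3 of the naming rule, so they stayed unnamed. Their median doublet score was 0.065 against 0.038 in cardiomyocytes and their median UMIs 3120.5 against 2245, and doublets of cardiomyocytes with other cells were not excluded. These nuclei read Mki67, a marker of dividing cells, at 1217 CPM against 16.2 in cardiomyocytes, Top2a, a topoisomerase of dividing cells, at 1090 against 10.6, and the sarcomere gene Ttn at 20037 against 31836. They numbered 1, 69, 105 and 67 in Ctl 1, Ctl 2, KO 1 and KO 2, which is 0.042% (Wilson 95% interval 0.0074 to 0.238), 1.29% (1.02 to 1.63), 2.16% (1.79 to 2.61) and 1.52% (1.20 to 1.92) of the sum of cardiomyocyte nuclei and these. The means were 0.665 ± 0.881% and 1.84 ± 0.46% (exact permutation p = 0.333). Ctl 1 was low in the whole cluster, with 0.256% of its nuclei against 1.64% in Ctl 2, 1.08% in KO 1 and 1.10% in KO 2. These nuclei were picked out after the data were seen.

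The make-up of the nuclei was compared to see whether cell classes took different shares in KO hearts. Cardiomyocytes made up 14.2 and 10.4% of nuclei in Ctl and 5.92 and 6.61% in KO (12.3 ± 2.7% and 6.27 ± 0.49%, log2 -0.97 ± 0.33, adjusted p = 0.0639). An unnamed cluster rich in background RNA, whose highest marker list was that of fibroblasts and whose leading genes were Col24a1 and Col11a1, rose from 6.60 ± 1.18% in Ctl to 14.1 ± 0.63% in KO (log2 1.09 ± 0.33, adjusted p = 0.0372). It was the 1 called of 22 classes and clusters, and its size and the level of Col11a1 are not separate results. That call ended with the replicate block (adjusted p = 0.0747), with TMM across classes (0.05001) and without Ctl 1 (0.415), Ctl 2 (0.0642), KO 1 (0.796) or KO 2 (0.938). Without Ctl 2 the 1 share called was that of the cluster led by cell cycle genes (log2 2.09, adjusted p = 0.0438), against 0.19 with all 4 animals. Fibroblasts took 14.4 ± 2.4% and 15.03 ± 0.40%, or 20.8 and 30.5% in Ctl and 34.4 and 36.6% in KO with background-rich clusters counted in, macrophages 10.3 ± 0.55% and 10.03 ± 2.3%, and endothelial cells 7.43 ± 4.04% and 5.79 ± 1.94%. No other share had an adjusted p under 0.967, and the exact permutation test cannot go below 0.333.

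**Figure D4:**
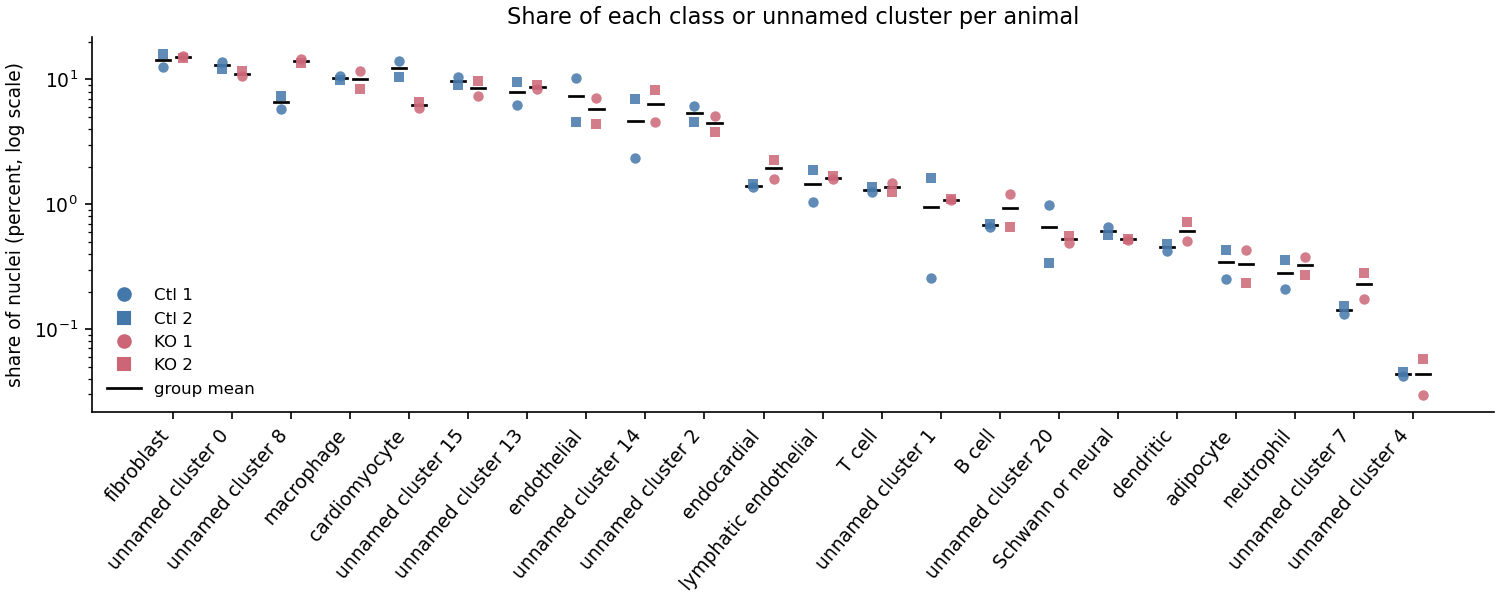
Share of nuclei in each class or unnamed cluster (percent, vertical log axis), ordered by mean share along the horizontal axis, with a point per animal and a black line at the group mean. Cardiomyocytes took 10.4 and 14.2% in Ctl and 5.92 and 6.61% in KO.

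In fibroblasts, the cells that lay down the scar, fatty acid oxidation genes were lower in KO as a group, with 23 of 23 members negative and a median of -0.44 (adjusted p = 4.4e-17; adjusted p = 0.625 with an estimated correlation), with log2 folds of -0.61 ± 0.28 for Lpl, -0.50 ± 0.19 for Hadha, of the mitochondrial trifunctional protein, and -0.52 ± 0.19 for Cd36. All 23 lay below their level in empty barcodes, where the median of the list was -0.487, as did 19 of the 20 mature sarcomere genes and 13 of the 14 fetal and stress genes. Matrix genes had 24 of 27 positive and a median of 0.36 (adjusted p = 1.5e-12; adjusted p = 0.724 with an estimated correlation). Among them Col3a1 was at 7130 ± 3597 CPM in Ctl and 7797 ± 1354 in KO, and Col1a2 and Sparc had log2 folds of 0.36 ± 0.41 and 0.27 ± 0.40. The fibroblast sums left out background-rich clusters of 25369 and 12999 nuclei with fibroblast markers as their highest list. Col24a1 and Col11a1 led the first, and Thbs4, Col12a1, Ltbp2 and Cilp were among the leading genes of the second. The lists were not tested with these clusters counted in. Mature sarcomere genes had 17 of 20 negative and a median of -0.26 (adjusted p = 1.1e-06; adjusted p = 0.724 with an estimated correlation), with -0.60 ± 0.35 for the giant sarcomere protein Ttn, -0.81 ± 0.30 for the adult myosin Myh6 and -0.24 ± 0.23 for the tropomyosin Tpm1. Cardiomyocyte markers were lower in the same sums, with 14 of 14 negative and a median of -0.46 (adjusted p = 3.7e-09; adjusted p = 0.508 with an estimated correlation), and macrophage markers were higher (8 of 12 positive, adjusted p = 0.0291; adjusted p = 0.826 with an estimated correlation). Atrial cardiomyocyte markers (3 of 3 positive, median 0.33) and erythroid markers (5 of 5, median 0.38) were higher as well, each at an adjusted p of 0.0291 and at 0.508 with an estimated correlation.

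The fetal and stress program had 10 of 14 members positive in fibroblasts and a median of 0.37 (adjusted p = 4.7e-05; adjusted p = 0.862 with an estimated correlation; 0.0664 without Ctl 1). Nppa, the atrial natriuretic peptide, was at 140 ± 19.4 CPM in Ctl and 242 ± 23.6 in KO, and Ankrd1 and Xirp2 had log2 folds of 0.51 ± 0.26 and 0.31 ± 0.21. Calcium handling was lower (adjusted p = 0.00029), as were oxidative phosphorylation (0.0038) and glycolysis (0.0152), and the recruited myeloid list was higher (0.0274). With an estimated correlation the adjusted p was 0.961 for the first 3 of these and 0.724 for the last. Calcium handling was not called without Ctl 1 (0.716) or KO 2 (0.224), oxidative phosphorylation without Ctl 2 (0.745) or KO 1 (0.234), glycolysis without Ctl 2 (0.740) or KO 1 (0.432), and the myeloid list without Ctl 1 (0.267), Ctl 2 (0.117) or KO 2 (0.347). Other fibroblast lists had adjusted p from 0.0520, for G2 and M phase, to 0.984. With the replicate block G2 and M phase (0.0156), ribosomal proteins (0.0082) and interferon response (0.0113) passed as well, each at an adjusted p of 0.961 with an estimated correlation and no block. Without Ctl 1 G2 and M phase (7.0e-06) and ribosomal proteins (0.0012) turned lower.

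Among single fibroblast genes, Col6a6, a chain of collagen VI, was at 135 ± 8.8 CPM in Ctl and 47.3 ± 6.3 in KO (log2 -1.49 ± 0.21), and Hmcn2, a hemicentin of the matrix, at 188 ± 3.1 and 54.6 ± 26.8 CPM (-1.76 ± 0.35). Ret, a receptor of neurotrophic factors, was at 27.1 ± 3.0 and 8.94 ± 0.37 CPM (-1.57 ± 0.20), and Dnase1l2 at 3.21 ± 0.19 and 0.703 ± 0.126 CPM. Dynlt1b, a dynein light chain gene on chromosome 17, had 6 and 38 UMIs in Ctl and 0 in both KO sums. It was at least 36.0-fold lower with the limit of 3 counts taken over the group. edgeR called 0 of 15502 genes, with 313 at an unadjusted p under 0.05, and DESeq2 called 9. With the replicate block 57 genes passed, 27 higher and 30 lower, and Col6a6 (adjusted p = 0.00030), Hmcn2 (0.0011), Ret (0.0017), Dynlt1b (0.0068) and Nppa (0.0262) were among them. Adjusted over the list alone 0 genes passed, and with the block 16 fatty acid oxidation genes, all lower, and 11 matrix genes, all higher, did. The count over all genes was 34 without Ctl 1, 94 without Ctl 2, 23 without KO 1 and 24 without KO 2.

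In endothelial cells, matrix genes were higher in KO, with 25 of 27 positive and a median of 0.54 (adjusted p = 1.0e-23; adjusted p = 0.489 with an estimated correlation). Adjusted over the list alone 8 of them passed, all higher, against 0 over all genes. They included Col12a1, a collagen that binds fibrils (13.3 ± 2.2 CPM in Ctl and 31.4 ± 3.4 in KO), Cilp, a matrix protein of cartilage and scar (log2 1.08 ± 0.23), Cthrc1, a secreted protein of activated fibroblasts (1.26 ± 0.33), and the collagen Col11a1 (1.84 ± 0.48). These 4 genes lay at 0.170, 0.196, 0.334 and 0.153 times their level in empty barcodes. Fibroblast markers were higher in the same sums, with 12 of 12 positive and a median of 0.47 (adjusted p = 2.5e-08; adjusted p = 0.471 with an estimated correlation), and macrophage markers too (10 of 10 positive, adjusted p = 6.1e-05; adjusted p = 0.523 with an estimated correlation). Fatty acid oxidation had 22 of 23 negative and a median of -0.56 (adjusted p = 4.6e-17; adjusted p = 0.489 with an estimated correlation), with log2 folds of -0.40 ± 0.36 for Cd36, -0.64 ± 0.32 for Lpl and -0.65 ± 0.21 for Hadha. Of these 23 genes 22 lay below their level in empty barcodes, where the median was -0.487. Cardiomyocyte markers were lower, with 13 of 14 negative and a median of -0.47 (adjusted p = 7.0e-08; adjusted p = 0.523 with an estimated correlation).

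Mature sarcomere genes were also lower in endothelial cells (adjusted p = 1.3e-07), and the fetal and stress program (1.8e-07) and resting fibroblast genes (6.1e-06, 18 of 18 positive) were higher, each at 0.489 with an estimated correlation. Calcium handling (adjusted p = 0.00041) and oxidative phosphorylation (0.00063) were lower, and hypoxia (0.0015), recruited myeloid (0.0041), angiogenic (0.0079), ribosomal (0.0187), TGF beta (0.0406) and resident macrophage (0.0439) lists were higher. With an estimated correlation the adjusted p of these 8 lists ran from 0.489 to 0.958. Without Ctl 1 the adjusted p was 0.190 for resting fibroblast, 0.902 for calcium handling, 0.0504 for hypoxia, 0.330 for recruited myeloid, 0.841 for angiogenic and 0.720 for resident macrophage genes, and ribosomal genes turned lower (0.0039). Without Ctl 2 it was 0.439 for oxidative phosphorylation and 0.575 for TGF beta, without KO 1 it was 0.208 and 0.211 for the same lists, and without KO 2 it was 0.270 for angiogenic, 0.655 for ribosomal and 0.179 for resident macrophage genes. Other lists had adjusted p from 0.140 to 0.879.

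The endothelial genes with the smallest p did not pass. Camk2b, a calcium-dependent kinase, was at 9.96 ± 4.97 CPM in Ctl and 0.978 ± 0.273 in KO, and Eps8l1, an actin regulator, at 13.01 ± 0.66 and 34.2 ± 3.7 CPM. Slit2, a guidance ligand, Ahnak2 and Ccn4, a secreted matricellular protein, had log2 folds of 1.42 ± 0.28, 1.33 ± 0.26 and 1.63 ± 0.34, at 0.173, 0.263 and 0.455 times their level in empty barcodes. edgeR called 0 of 11710 genes, with 283 at an unadjusted p under 0.05, and DESeq2 called 0. The edgeR count was 13 without Ctl 1, 109 without Ctl 2, 13 without KO 1, 9 without KO 2 and 0 with the replicate block.

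In macrophages, matrix genes were higher in KO, with 26 of 27 positive and a median of 0.86 (adjusted p = 3.4e-33; adjusted p = 0.680 with an estimated correlation). Col12a1 was at 32.6 ± 9.7 CPM in Ctl and 92.2 ± 16.9 in KO (log2 1.48 ± 0.28), and Cilp, Col11a1 and the TGF beta binding protein Ltbp2 had log2 folds of 1.19 ± 0.25, 0.99 ± 0.26 and 1.10 ± 0.31, at 0.461, 0.4997, 0.432 and 0.494 times their level in empty barcodes. Adjusted over the list alone 7 matrix genes passed, all higher, against 0 over all genes, and 22 with the replicate block. Of the members, 26 lay below their level in empty barcodes, and fibroblast markers were higher in the same sums (11 of 12 positive, median 0.58, adjusted p = 1.6e-07; adjusted p = 0.652 with an estimated correlation). Endothelial markers were higher too (11 of 11 positive, adjusted p = 0.0284; adjusted p = 0.667 with an estimated correlation) and cardiomyocyte markers lower (11 of 14 negative, adjusted p = 0.0473; adjusted p = 0.618 with an estimated correlation). Also higher were endocardial (5 of 6 positive, median 0.56, adjusted p = 0.00034), Schwann or neural (3 of 3, 0.0284) and erythroid markers (5 of 5, 0.0284), at adjusted p of 0.618, 0.618 and 0.667 with an estimated correlation.

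S phase genes had 41 of 43 members negative in macrophages (adjusted p = 3.7e-06; adjusted p = 0.871 with an estimated correlation), and G2 and M phase genes 53 of 54, with a median of -0.41 (adjusted p = 0.00031; adjusted p = 0.925 with an estimated correlation). Mki67 was at 169, 638, 236 and 265 CPM in Ctl 1, Ctl 2, KO 1 and KO 2, Top2a, a topoisomerase of dividing cells, at 85.3, 287, 106 and 148, and the condensin subunit Smc4 at 202, 325, 249 and 235. The cell cycle calls rested on Ctl 2. Without it S phase was not called (0.149) and G2 and M phase turned higher (6.9e-05). G2 and M phase was not called without KO 1 either (0.0622). Resident macrophage genes had 10 of 12 negative and a median of -0.21 (adjusted p = 0.0041; adjusted p = 0.686 with an estimated correlation), with log2 folds of -0.32 ± 0.31 for the mannose receptor Mrc1, -0.39 ± 0.32 for F13a1, a clotting factor chain, and -0.16 ± 0.26 for the scavenger receptor Stab1. That call ended without Ctl 2 (0.289) and without KO 1 (0.176).

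Fatty acid oxidation had 23 of 23 negative in the macrophage sums (adjusted p = 5.5e-09; adjusted p = 0.680 with an estimated correlation), and the fetal and stress program 11 of 14 positive (adjusted p = 6.5e-09; adjusted p = 0.686 with an estimated correlation). All 23 and all 14 lay below their level in empty barcodes, where the medians were -0.487 and 0.396. The fetal and stress list held Clu, a secreted chaperone found in many cell types, which alone passed over the list (137 ± 20.9 CPM in Ctl and 306 ± 60.1 in KO). Resting fibroblast (adjusted p = 8.5e-06), TGF beta (0.0019), ribosomal (0.0032), hypoxia (0.0132) and angiogenic (0.0138) lists were higher and calcium handling (0.0036) lower. With an estimated correlation the adjusted p of these 6 lists ran from 0.680 to 0.925. Without Ctl 1 the adjusted p was 0.825 for resting fibroblast, 0.797 for calcium handling, 0.433 for hypoxia and 0.876 for angiogenic genes, and ribosomal genes turned lower (0.0176). Without Ctl 2 it was 0.147 for TGF beta. Without KO 1 it was 0.157 for TGF beta and 0.114 for hypoxia, and without KO 2 it was 0.503 for ribosomal, 0.157 for calcium handling, 0.0519 for hypoxia and 0.197 for angiogenic genes. Other lists had adjusted p from 0.0638, for recruited myeloid, to 0.882, and mitochondrially encoded genes passed with the replicate block (0.0063; adjusted p = 0.925 with an estimated correlation and no block).

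Among single macrophage genes, Dynlt1b had 8 and 18 UMIs in Ctl and 0 in both KO sums, at least 22.4-fold lower. Rnaset2b, a lysosomal ribonuclease on chromosome 17 like Dynlt1b, was at 11.4 ± 7.3 CPM in Ctl and 1.68 ± 0.31 in KO. Scd4, a fatty acid desaturase, was at 7.60 ± 1.33 and 2.04 ± 0.20. Sfrp2 was at 89.5 ± 26.6 and 231 ± 17.5 CPM, 0.547 times its level in empty barcodes. edgeR called 0 of 14287 genes, with 262 at an unadjusted p under 0.05, and DESeq2 called 0. With the replicate block 181 passed, 155 higher and 26 lower, among them Col12a1 (adjusted p = 1.5e-09), Rnaset2b (1.1e-06) and Scd4 (0.0045). Fitted with the block on genes above their level in empty barcodes alone, 19 passed, 7 higher and 12 lower. The edgeR count was 71 without Ctl 1, 362 without Ctl 2, 6 without KO 1 and 16 without KO 2.

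**Figure D5:**
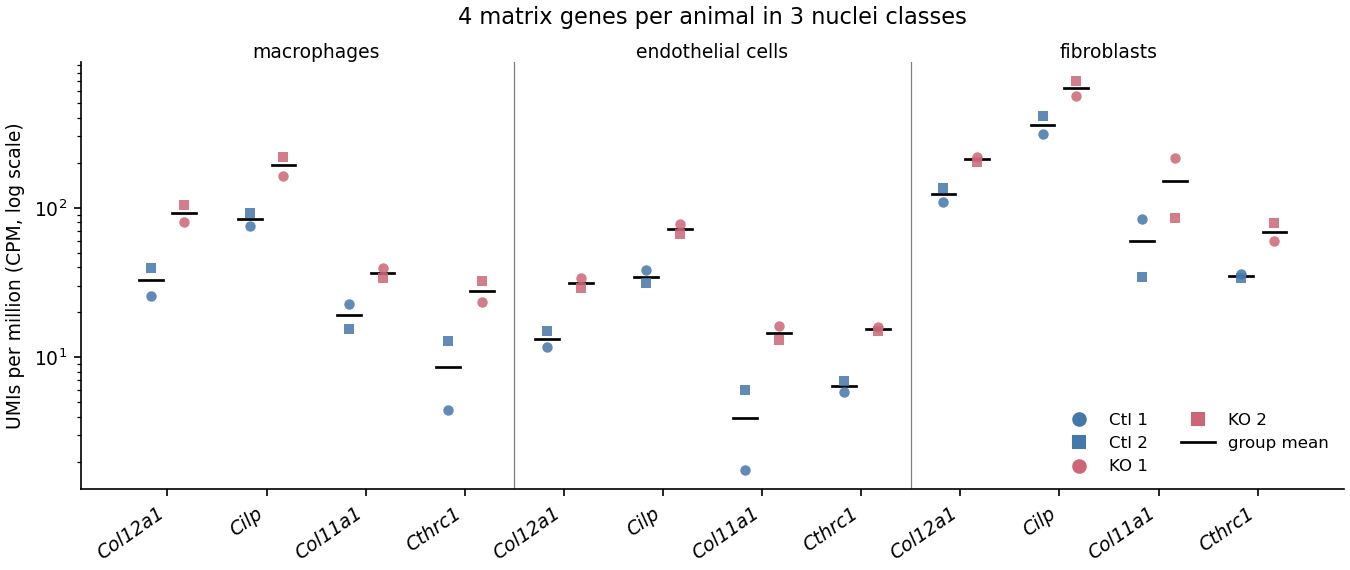
Levels of 4 matrix genes in CPM (vertical log axis) in macrophages, endothelial cells and fibroblasts (horizontal axis), with a point per animal and a black line at the group mean. Col12a1 in macrophages stood at 25.8 and 39.5 CPM in Ctl and at 80.2 and 104 CPM in KO. The fibroblast class left out background-rich clusters that had Col11a1, Col12a1 and Cilp among their leading genes.

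Over all nuclei, matrix genes were higher in KO, with 26 of 27 positive and a median of 0.68 (adjusted p = 2.9e-21; adjusted p = 0.561 with an estimated correlation), with log2 folds of 1.23 ± 0.18 for Col11a1, 0.95 ± 0.20 for Col12a1, 1.01 ± 0.23 for Cilp and 1.34 ± 0.31 for Cthrc1. Fatty acid oxidation had 24 of 24 negative (adjusted p = 5.7e-19), calcium handling 23 of 24 (1.2e-12) and mature sarcomere 19 of 20 (5.3e-07), each at an adjusted p of 0.561 with an estimated correlation. Cardiomyocyte markers were lower, with 14 of 14 negative and a median of -0.51 (adjusted p = 1.2e-08; adjusted p = 0.854 with an estimated correlation), fibroblast markers higher (10 of 12 positive, adjusted p = 0.0042; adjusted p = 0.854 with an estimated correlation), and cardiomyocytes made up 12.3% of nuclei in Ctl and 6.27% in KO, so these sums mix class shares with levels. The nuclear RNAs Malat1 and Neat1 were at 22465 and 1047 CPM in Ctl 1, 21847 and 747 in Ctl 2, 18519 and 682 in KO 1, and 18525 and 677 in KO 2, with log2 folds of -0.26 ± 0.27 and -0.40 ± 0.21 over all nuclei and -0.01 ± 0.27 and -0.10 ± 0.18 in cardiomyocytes. Strit1 was at 2.81 ± 0.66 CPM in Ctl and 0.438 ± 0.011 in KO, Cacna1h, a T-type calcium channel, at 2.94 ± 0.08 and 0.693 ± 0.082, and Dynlt1b at 39 and 168 UMIs in Ctl and 1 and 0 in KO. Msln and Upk3b, genes of the mesothelium, were at 0.249 ± 0.128 and 0.285 ± 0.044 CPM in Ctl and 3.03 ± 0.52 and 1.79 ± 0.24 in KO.

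edgeR called 0 of 21650 genes over all nuclei, with 1009 at an unadjusted p under 0.05, and DESeq2 called 72. Without Ctl 1, Ctl 2, KO 1 and KO 2 edgeR called 70, 980, 11 and 19, and 0 with the replicate block. Adjusted over the list alone 5 matrix genes passed, all higher, and 1 hypertrophic signaling gene, Adra1b, lower (log2 -1.57 ± 0.26). Oxidative phosphorylation (adjusted p = 3.4e-05), hypertrophic signaling (0.0261) and glycolysis (0.0328) lists were lower, and fetal and stress (0.00076), ribosomal (0.0026), G2 and M phase (0.0055), TGF beta (0.0055), recruited myeloid (0.0111), resting fibroblast (0.0204) and hypoxia (0.0446) lists were higher. With an estimated correlation the adjusted p of these 10 lists ran from 0.561 to 0.986. G2 and M phase turned lower without Ctl 1 (3.0e-22). Without Ctl 1 the adjusted p was also 0.103 for ribosomal, 0.614 for recruited myeloid, 0.751 for resting fibroblast, 0.197 for glycolysis and 0.524 for hypoxia genes, and without Ctl 2 it was 0.121 for hypertrophic signaling and 0.0822 for glycolysis. Without KO 1 it was 0.0975 for oxidative phosphorylation and TGF beta, 0.147 for recruited myeloid, 0.531 for hypertrophic signaling and 0.606 for glycolysis. Without KO 2 it was 0.180 for fetal and stress, 0.266 for ribosomal and resting fibroblast, and 0.468 for hypoxia genes. With the replicate block hypertrophic signaling (0.117) and hypoxia (0.0633) were not called, and cell cycle inhibitors (0.0449), splicing regulators (0.0474) and interferon response (0.0342) were, at an adjusted p of 0.750, 0.750 and 0.986 with an estimated correlation and no block. Other lists had adjusted p from 0.0788 to 0.983, with 0.980 for the sex linked genes.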

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

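The tests of depth for the matrix genes, all tests of the chromosome 17 stretch and the test of background clusters for the cardiomyocyte share were chosen only after the result was seen, as were the p limit of 0.01 and the window of 20 Mb.

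Dennd2c lies on chromosome 3, as does Mbnl1, and whether a stretch of that chromosome differs between the groups was not tested in cardiomyocytes. For Dennd2c the genotype effect in cardiomyocytes differed from that in other nuclei by 2.15 on the log2 scale, by a test of the difference itself (interaction term, adjusted p = 0.0269). Named classes alone as the other nuclei gave 2.47 and an adjusted p of 0.1999. Fibroblasts alone gave 1.81 and an adjusted p of 1. In all the alternatives for the log2 fold of Dennd2c, cardiomyocytes against other nuclei, the direction was the same, and the adjusted p ran from 2.7e-09 to 1.

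Matrix genes were higher in KO in the macrophage sums, with a median log2 fold of 0.86. A difference in depth between the sums was argued against. At the preset correlation of camera the list kept an adjusted p of 6.41e-24 after thinning to 1 depth. With an estimated correlation the list was not called at full depth. RNA from other cells may account for the pattern, since the median of the list in empty barcodes was 0.690 and 26 of 27 members lay below their level there. A change in the macrophages themselves cannot be told apart from it, because just 1 member lay at or above that level, with a log2 fold of -0.044. An effect of genotype on the cells that make matrix stays open, since in the fibroblast sums 25 of 27 members lay at or above that level with a median of 0.37, and the list passed (adjusted p = 1.5e-12) but not with an estimated correlation (adjusted p = 0.724). The fibroblast sums left out background-rich clusters that had matrix genes among their leading genes.

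Genes of a stretch of chromosome 17 differed between the groups over all nuclei, with 11 of 453 tested genes between 15 and 35 Mb at p under 0.01 against 3.90 expected. The highest count in 100 shuffled gene orders was 10 and the highest in windows of other chromosomes was 8. With 8 mesothelial markers left out, Msln among them, the window held 10 genes, as many as 4 of 100 shuffled orders reached (highest 12). The count allows a strain segment that differs between the groups but is close to chance. The overlapping window from 5 to 25 Mb held 8 of 232 genes against 2.00 expected. The highest count in shuffled orders was taken over all windows, those with more genes included. It therefore cannot judge the count in this smaller window. Dynlt1b, Rnaset2b and Rsph3b were among those 8, so Dynlt1b and Rnaset2b, named above in fibroblasts or macrophages, lie near this stretch. Of the 11 genes between 15 and 35 Mb, 10 were lower in KO, Cacna1h, Dnase1l2, Eci1 and Rpl3l among them, and Msln was higher. For 7 of the lower genes, those at or above their level in empty barcodes, a different mix of cell classes was argued against as the whole cause. Their median log2 fold was -1.285 in the cardiomyocyte sums, all of them lower. They were picked as lower over all nuclei, which include the same cardiomyocyte nuclei, so their direction was partly set beforehand. The mix may account for part in Rpl3l (-0.63 in cardiomyocytes against -1.22 over all nuclei), Gm35576 (-0.47 against -0.88) and Gm17276 (-0.46 against -0.77). It stays open for Eci1 (-0.21 in cardiomyocytes against -0.78 over all nuclei), Cacna1h (-5.02 against -2.09, with 0 and 0.19 CPM in KO cardiomyocytes), Grm4 and Msln, which are not among the 7. Reads shared between paralogs and an effect of MBNL1 loss or of the constructs on these genes stay open and were not tested.

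The share of cardiomyocyte nuclei had a log2 fold of -0.97 that did not pass (adjusted p = 0.0639), with both KO values below both Ctl values. Depth per nucleus was argued against, since the log2 fold was -0.955 among nuclei with at least 1000 UMIs. Placement of cardiomyocyte nuclei in background-rich clusters was argued against as the whole cause, since the KO shares stayed lower with those clusters counted in, by -7.85 percentage points (28.0 and 22.5% in Ctl, 16.5 and 18.3% in KO). It may account for part, since the log2 ratio of the means was then -0.54. The ratio was -0.43 with a cluster counted in as well that had markers of 2 classes. The highest marker list of that cluster was that of atrial cardiomyocytes. A loss of cardiomyocytes with genotype or a larger infarct stays open and was not tested.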

How the results depend on the processing

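Leaving out the nuclei with the highest 6% of doublet scores, wide classes, genes above their level in empty barcodes, named classes alone and the cycling nuclei with cardiomyocyte markers were tests chosen only after the data were seen. Keeping doublets, an alternative chosen beforehand, equals the reported values, since none were left out. With 1 animal left out, the lone animal of its group is assumed to vary like the others. For named genes, 99 log2 folds gave 1527 alternative values, of which 1348 kept their direction and side of the threshold, 127 newly passed, 2 no longer passed and 50 changed sign. For 10 lists in cardiomyocytes, 80 alternative values held 47 that kept both, 25 that lost the call, 5 that newly passed and 3 that changed direction. With 2 animals per group, 4-fold changes were mostly called in simulated data and 2-fold changes mostly not. Except where fewer samples or fewer genes make the difference, the cause was not tested.

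The count of 0 genes called by edgeR (618, 313, 283, 262 and 1009 at an unadjusted p under 0.05 in cardiomyocytes, fibroblasts, endothelial cells, macrophages and all nuclei) stayed at 0 with DESeq2 size factors, library totals alone, 500 or 1000 UMIs, 5% mitochondrial UMIs, thinned sums, top doublet scores left out, and wide classes where these were run. The DESeq2 Wald test called 16 in cardiomyocytes, 9 in fibroblasts, 0 in endothelial cells, 0 in macrophages and 72 in all nuclei. Without filterByExpr the counts were 0, 83, 37, 49 and 6. The replicate block gave 0, 57, 0, 181 and 0. Among genes above their level in empty barcodes 0 passed, and with the replicate block 3, 178, 30, 19 and 0 did. Leaving out 1 animal gave 2 to 274 in cardiomyocytes, 23 to 94 in fibroblasts, 9 to 109 in endothelial cells, 6 to 362 in macrophages and 11 to 980 in all nuclei, with the highest count without Ctl 2 in every class. For cardiomyocytes against other nuclei the count of 1 became 35 without filterByExpr, 0 with fibroblasts alone, 0 with named classes alone and 2 to 579 with 1 animal left out.

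Lists called numbered 8 in cardiomyocytes, 8 in fibroblasts, 13 in endothelial cells, 12 in macrophages and 14 in all nuclei. With an estimated correlation 0 were called in each, and with fry 0. Leaving out 1 animal gave 5 to 14, 6 to 12, 12 to 16, 10 to 15 and 10 to 17. In thinned sums the adjusted p was 0.291 for interferon response in cardiomyocytes, 0.304 for glycolysis in fibroblasts, 0.143 for TGF beta, 0.0808 for angiogenic, 0.122 for hypoxia and 0.599 for resident macrophage genes in endothelial cells, and 0.141 for hypoxia in all nuclei, each called at full depth. With 1 animal left out, the adjusted p of the S phase list in cardiomyocytes ran from 0.00178 to 0.850 and that of the G2 and M phase list from 5.16e-10 to 0.134, each with directions both ways.

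The count of called class shares went from 1 to 0 with TMM across classes, 500 UMIs, 1000 UMIs, the replicate block and top doublet scores left out, and without Ctl 1, KO 1 or KO 2. Without Ctl 2 it was 1, which was the cluster led by cell cycle genes (log2 2.09, adjusted p = 0.0438) and not the unnamed fibroblast-like cluster. The log2 fold of the unnamed fibroblast-like cluster was 1.11, 1.09, 1.09, 1.10 and 1.07 under the first 5 of these and 0.92 to 1.29 with 1 animal left out, against 1.09. Its adjusted p was 0.05001, 0.111, 0.215, 0.0747 and 0.120, and 0.0642 to 0.938 with 1 animal left out. The log2 fold of the cardiomyocyte share, which did not pass (adjusted p = 0.0639), ran from -0.96 to -0.95 under the same 5 settings, at adjusted p of 0.0897, 0.138, 0.319, 0.117 and 0.140, and from -1.18 to -0.73 with 1 animal left out, at adjusted p from 0.0642 to 0.938. The differences in cardiomyocyte nuclei with cell cycle transcripts, KO minus Ctl in percentage points, were larger unthinned, at 8.97 and 8.25 for at least 1 and 2 UMIs of G2 and M phase and 5.21 and 5.03 for S phase, since KO 1 had the deepest nuclei. For S phase at 2 UMIs thinning to 500 gave -0.194, and for G2 and M phase at 2 UMIs adding the cycling nuclei gave 1.12. With 1 animal left out they ran from -0.658 to 2.05 and from -0.442 to 0.468 for G2 and M phase, and from -0.618 to 0.278 and from 0.111 to 0.340 for S phase.

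None of the log2 folds that changed sign was called. In cardiomyocytes, leaving out 1 animal gave -0.27 to 0.019 for Mbnl2, -0.67 to 0.49 for Mbnl3, -0.26 to 0.73 for Ppargc1a, -0.35 to 0.058 for Cd36, -0.31 to 0.28 for Sdha, -0.078 to 0.12 for Ryr2, -0.23 to 0.66 for Vegfa and -0.086 to 0.092 for Egln1. In fibroblasts it gave -0.14 to 0.28 for Mbnl1, -0.34 to 0.85 for Col3a1 and -0.092 to 0.75 for Sparc. In endothelial cells it gave -0.12 to 0.22 for Mbnl1, -0.21 to 0.077 for Mbnl2, -0.90 to 0.95 for Mbnl3 and -0.99 to 0.0094 for Cd36. In macrophages it gave -0.71 to 0.19 for Mbnl1, -0.28 to 0.18 for Mbnl2, -0.50 to 0.34 for Mbnl3, -1.35 to 0.61 for Mki67, -0.43 to 0.31 for Smc4 and -1.18 to 0.62 for Top2a. In all nuclei it gave -0.14 to 0.24 for Mbnl1 and -0.023 to 0.42 for Mbnl3, and in cardiomyocytes against other nuclei -0.019 to 0.33 for Mbnl1.

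Under other settings, Mbnl3 in cardiomyocytes was -0.034 with the replicate block and -0.00035 with top doublet scores left out. Wide classes gave -0.039 for Ppargc1a, -0.225 for Ryr2, -0.053 for Vegfa and -0.177 for Egln1 in cardiomyocytes, and Egln1 was -0.0080 with DESeq2 size factors and -0.0038 at 5% mitochondrial UMIs. Mbnl3 in endothelial cells was 0.122 at 1000 UMIs. In macrophages Mbnl2 was 0.055 in thinned sums, and Mbnl3 was -0.039 at 500 UMIs, -0.178 at 1000 UMIs, -0.405 in thinned sums and -0.098 with the replicate block.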

Other observations

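Apart from the levels of sex linked and immediate early genes, the tests and counts here were chosen only after the data were seen. Genes of the epicardium and mesothelium, the outer lining of the heart, were higher in KO over all nuclei. Of their marker list 8 of 8 members were positive, with a median log2 fold of 2.59 (adjusted p = 7.0e-34; adjusted p = 0.539 with an estimated correlation). The UMIs of 7 of these genes came to 2.35, 2.45, 15.9 and 10.1 CPM in Ctl 1, Ctl 2, KO 1 and KO 2. Nuclei with at least 3 such UMIs numbered 3, 5, 163 and 58, or 0.018, 0.0098, 0.203 and 0.088% of nuclei. An unnamed cluster led by Msln and Upk3b held 164, 171, 396 and 369 nuclei, of which 3, 2, 84 and 49 had at least 3. The cluster as a whole took 0.978, 0.335, 0.493 and 0.561% of nuclei in Ctl 1, Ctl 2, KO 1 and KO 2. Its share was thus not called higher in KO (log2 fold of the share -0.30 ± 0.56, adjusted p = 0.967).

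Endocardial markers were higher in KO over all nuclei, with 6 of 6 positive and a median of 0.42 (adjusted p = 0.0013; adjusted p = 0.539 with an estimated correlation). Mast cell genes (Cpa3, Cma1, Mcpt4) led an unnamed cluster of 425 nuclei, with 22, 78, 139 and 186 in Ctl 1, Ctl 2, KO 1 and KO 2 (log2 fold of the share 0.67 ± 0.54, adjusted p = 0.967). Another unnamed cluster of 92 nuclei, 7, 23, 24 and 38 per library, read 12.4% of its UMIs from chromosome 9 against 4.72% elsewhere. In it, chromosome 9 genes that stood under 0.5 CPM in the other nuclei summed to 6775 CPM against 81.5.

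Immediate early Egr1 was at 64.4 CPM in Ctl 1 and 238, 195 and 176 in Ctl 2, KO 1 and KO 2, and Fos at 22.3, 43.9, 30.3 and 21.1 CPM. Xist was at 328, 169, 253 and 191 CPM and transcripts of 4 Y-linked genes were under 0.16 CPM in each library. The Mbnl1-tg construct was at 0.159, 0.158, 0.117 and 0.112 CPM, and Cre and Tta were at 0 in all 4. The tdTomato construct was at 3.39 CPM in Ctl 2 and 0 in the others. Within 10 Mb of Mbnl1, 3 of 130 tested genes (Strit1, Mme and Noct) had p under 0.01 over all nuclei, against 1.12 expected.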
